A study of Mus musculus with 8 samples.

How the data were processed

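Total RNA longer than 200 nt was extracted with Trizol from splenic lymphoma cells sorted for B220 and green fluorescent protein, per the labels. Libraries were made with a stranded kit for total RNA with removal of ribosomal RNA. The design has 8 libraries, 4 with a scramble shRNA and 4 with shCrebbp, and replicates were numbered in the order in which the series lists them. Per the submitters' processing notes, CASAVA 1.8, TopHat2, Cufflinks and the genome build mm10 were used. The notes give neither the role nor the parameters of each. The authors deposited 1 table with FPKM per locus and library. The unit was inferred from the values and from the form of the locus identifiers, since the header names none. How values were scaled to the fragments sequenced is not stated.

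The table had 25478 lines, of which 1 was emptied and not used here. It held 13 sample columns, of which 8 matched the samples by name and 5 matched no sample and were not used. Values stood in the table for single libraries, with no fold change or p-value columns, so no comparison by the authors was described. Of the 25477 loci, 3460 shared a gene name with another locus, 421 merged several genes and 1217 were small RNAs. Among the loci tested these numbered 1755, 311 and 258. Locus starts were converted to count from 1, and a locus can extend beyond the gene it is named for. Values over 100000 FPKM occurred at 12 loci, and the highest was 6008140 for Napg in scramble 2. Since most such loci are small RNAs or were seen in 1 library, no totals of FPKM were compared. Exact values of 0 at genes that all cells use can be failed estimates and were kept as listed.

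FPKM gives no counts, so precision was read from replicates alone and no counting interval was computed. Relative depth was estimated from low values. For each library, the densest log2 ratio (window 0.05) to shCrebbp 4 was taken over loci in the lowest 12% of values of both libraries. Relative to shCrebbp 4, set to 100%, this gave 161, 68.8, 116 and 110% for scramble 1 to 4, and 73.7 and 225% for shCrebbp 1 and 2. For shCrebbp 3 the value of 215% was unresolved, as its peak held 4.16% of low values.

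Values were transformed as log2(FPKM + 1), and loci with a mean of at least 1 FPKM over the 8 libraries were kept (11417). Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean trend, two-sided), with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. Single genes were also compared with an exact permutation test over the 70 divisions of the libraries, whose smallest two-sided p is 0.0286. The name prefixes were fitted as 3 coefficients in the same way. They are nested in the groups and could not be a covariate. No paired analysis was possible because the labels pair no libraries.

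Before the data were examined, 30 gene lists, the named-gene rule, the tests and most alternatives were fixed. The rule took Crebbp and Ep300, then genes past the threshold. With fewer than 5 in a direction, it took up to 10 of smallest p whose groups did not overlap, given as not passing. It added 2 to 4 members of each list by p and a set of anchor genes. Predicted genes and small RNAs were passed over. The rule was first coded to leave out merged loci and was recoded to its wording after values were seen, which added the loci of Amigo3 with Gmppb and of Pygo2 with Shc1. How list symbols map to merged or repeated loci was set after the gene names, not the values, had been seen. Lists with at least 5 members tested were compared by camera with a preset correlation of 0.01, and beside it by camera with an estimated correlation and by fry, each with Benjamini-Hochberg adjustment over the 23 lists. A list score is the mean over members of log2(FPKM + 1) minus its mean over the 8 libraries.

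The fit was tested on simulated data with the spread of these libraries, in 20 draws with 200 changed genes each and genes drawn independently. At an adjusted p under 0.05 it recovered 38.4% of 2-fold and 78.9% of 4-fold changes, with a mean of 6.35 false calls. Signs of the changed genes were right for 99.0%. A list shifted by 0.5 on the log2 scale, that of cell cycle genes, was called by camera in 20 of 20 draws, with a mean of 0.1 other lists. In the real libraries members of a list can vary together (estimated correlation 0.68 for this list), so these list results do not carry over.

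Alternatives covered pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, loess removal of a trend with expression, a prior without trend, library weights, summed loci of a symbol, other thresholds, each name prefix alone and each library left out in turn. Added after seeing the data were a robust prior, leading loci of single genes only, leaving out scramble 2 and shCrebbp 3, an exact test of list scores, and 10000 random lists matched on expression. Figures were drawn with Python 3.11.15.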

Results

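RNA was sequenced from mouse lymphoma cells taken from the spleen and sorted for B220, a B cell surface marker, and for green fluorescent protein. Cells of 4 libraries carried a scramble short hairpin RNA (shRNA), which targets no gene, and cells of 4 libraries carried an shRNA against Crebbp (shCrebbp). Crebbp encodes a histone acetyltransferase that acts as a coactivator of transcription. Expression was given as fragments per kilobase of transcript, scaled to the sequenced fragments (FPKM) at 25477 loci of the mm10 genome build. Read counts were not given, so the absolute depth of each library is unknown. The share of loci at 0, which falls with depth, was 43.4, 51.8, 43.9 and 42.4% in scramble libraries 1 to 4, and 46.0, 36.3, 33.2 and 43.8% in shCrebbp libraries 1 to 4. The names of shCrebbp libraries 1 and 2 begin with AO228, those of shCrebbp 3 and 4 with AO229, and those of all scramble libraries with AO227. The labels do not say what these prefixes stand for, and no prefix holds both groups. Nor do they say that each library came from its own animal, so p-values measure the spread between these libraries.

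The first comparison addressed the targeted gene itself. Crebbp (chromosome 16, 4081237 to 4213404) measured 25.9 ± 5.54 FPKM in scramble and 22.0 ± 3.66 in shCrebbp cells (SD, n = 4 each). The log2 difference was -0.22, with a standard error of 0.18 and a 95% confidence interval from -0.62 to 0.19. An exact two-sided permutation test gave p = 0.314, where the smallest p that 4 against 4 libraries allow is 0.0286. The scramble libraries held 33.7, 22.9, 21.3 and 25.8 FPKM, and the shCrebbp libraries 18.9, 26.6, 23.4 and 19.3. A lower Crebbp transcript level was thus not detectable, and the interval excludes a fall beyond -0.62 on the log2 scale. Protein was not measured. Ep300, the gene of the closely related acetyltransferase p300 (chromosome 15, 81585304 to 81652452), measured 18.7 ± 3.04 FPKM in scramble and 21.1 ± 3.81 in shCrebbp (SD, n = 4 each; log2 difference 0.16, exact permutation p = 0.429).

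The second comparison asked, as the series title frames it, whether genes are repressed when Crebbp is targeted. The clearest differences lay in genes that cells switch on quickly after a stimulus or heat stress, and in target genes of NF-kappaB, the transcription factor activated through CD40. Both gene lists, fixed before the data were examined, fell in shCrebbp cells. Egr2, an early response transcription factor, measured 97.4 ± 12.98 FPKM in scramble and 48.5 ± 8.83 in shCrebbp (SD, n = 4 each). Hspa1a, which encodes the inducible chaperone Hsp70, measured 383 ± 102 and 127 ± 71.7 FPKM. Nfkbia, whose product IkappaB alpha holds NF-kappaB in the cytoplasm, measured 276 ± 31.0 and 149 ± 17.4 FPKM.

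Gene by gene, limma called 0 of the 11417 loci tested at an adjusted p under 0.05, and the smallest adjusted p was 0.521. At an unadjusted p under 0.05 there were 573 loci, where 570.85 are expected by chance. Of these, 335 (58.5%) were lower and 238 higher in shCrebbp cells. The lower share was 50.4% after quantile normalization and 44.9% without a filter on low values. In 379 loci (3.32%) the values of the groups did not overlap, against 2.86% by chance, with 199 lower and 180 higher. Among loci at an unadjusted p under 0.05 that differed more than 2-fold, 82 were lower and 47 higher. The counts in each direction are thus descriptive, since no single gene passed the test over all genes.

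The genes of smallest p with separated groups are given as values, since none passed. Separated groups always give the smallest possible exact permutation p of 0.0286, so for genes chosen this way that p adds no support. Dnaja1 (chromosome 4, 40720154 to 40757885), which encodes a cochaperone of Hsp70, measured 117 ± 13.6 FPKM in scramble and 57.2 ± 8.47 in shCrebbp (log2 difference -1.02, standard error 0.15; limma adjusted p = 0.521). Marcksl1 (chromosome 4, 129513581 to 129515981), a gene of the MARCKS family of actin regulators, measured 173 ± 24.8 and 92.7 ± 7.30 (log2 difference -0.89). For Nfkbia the difference was -0.88 and for Egr2 -0.998 (chromosome 10, 67537061 to 67542314). The locus of Nfkbia runs from 55280814 to 55492721 on chromosome 12, far beyond the gene. Dnajb9, a gene of the endoplasmic reticulum chaperone ERdj4, measured 92.1 ± 6.27 and 55.4 ± 5.43 FPKM (log2 difference -0.73). Mt1, which encodes the metal-binding protein metallothionein 1 (chromosome 8, 94179089 to 94180507), measured 26.2 ± 11.4 and 5.77 ± 2.37 FPKM (log2 difference -1.96; limma adjusted p = 0.577). The zinc importer gene Slc39a4 measured 4.66 and 0.316 FPKM. The log2 difference was -1.27 for Sirpa, a receptor for CD47, -0.88 for the potassium channel gene Kcnk5, and -0.87 for the merged locus of Amigo3 and Gmppb.

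The genes of smallest p in the other direction each had a limma adjusted p of 0.915. Ndufa8, a subunit gene of respiratory complex I, measured 10.1 ± 1.14 FPKM in scramble and 15.2 ± 1.25 in shCrebbp (log2 difference 0.54, n = 4 each). Dtx3l, a ubiquitin ligase gene, measured 6.40 ± 0.932 and 11.5 ± 3.07 (log2 difference 0.73). Log2 differences were 0.65 for Gphn, 0.63 for Dcxr, 0.61 for Pigu, 0.58 for Ttc5 and 0.56 for the merged locus of Pygo2 and Shc1. The log2 difference was 1.22 for Sbsn (0.215 and 1.93 FPKM), 1.11 for Bicd1 (0.579 and 2.48) and 0.95 for Macrod1 (1.11 and 3.15), which all lay near the filter of 1 FPKM.

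**Figure D1:**
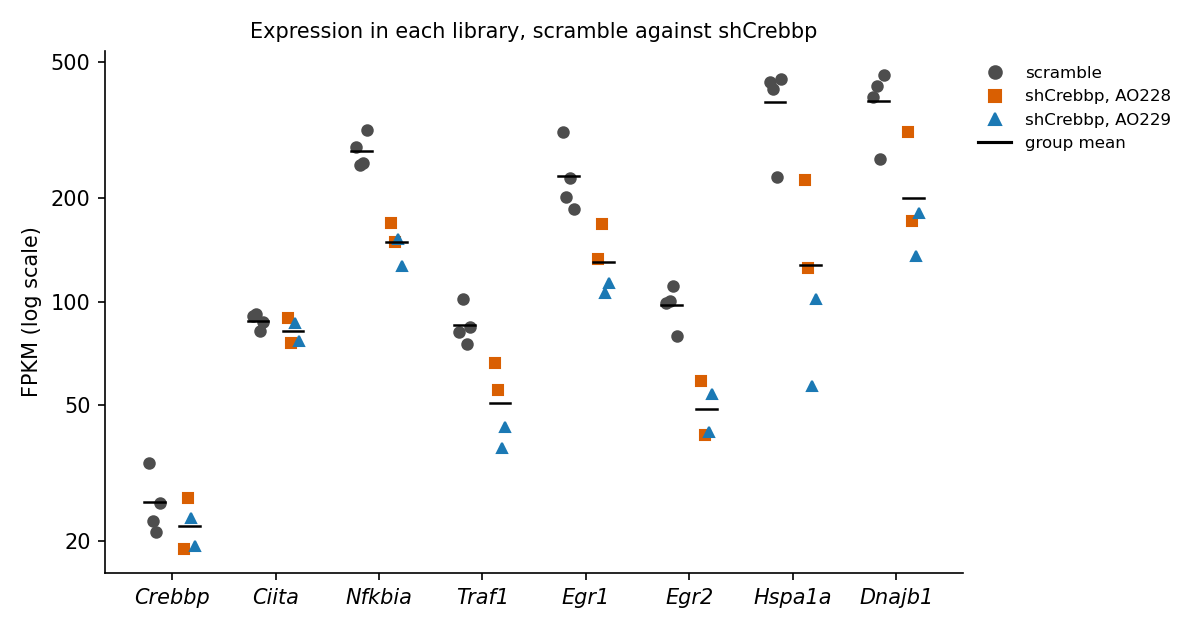
FPKM on a log scale for 8 genes (horizontal axis), with 1 point per library: circles are scramble, squares shCrebbp AO228 and triangles shCrebbp AO229, and black lines are group means. All 4 shCrebbp libraries lie below all 4 scramble libraries for Nfkbia, Traf1, Egr1, Egr2 and Hspa1a, while the groups overlap for Crebbp, Ciita and Dnajb1.

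Of 30 gene lists fixed in advance, 23 had at least 5 members above the filter, and camera called 9 at an adjusted p under 0.05. Of the 35 ways to divide the 8 libraries into groups of 4, 8 gave as many called lists. Only the immediate early and heat shock list and the NF-kappaB list kept their call with an estimated correlation between genes. No member of any list passed limma over all genes, while 13 members of 5 lists passed when adjusted over the list alone.

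The immediate early and heat shock list fell, with 19 of 20 members lower and a median log2 change of -0.43 (camera adjusted p = 1.0e-09, 0.0131 with an estimated correlation, and fry adjusted p = 0.0199). Its score was lower in all 4 shCrebbp libraries than in any scramble library. Adjusted over the list alone, 6 members passed, against 0 over all genes: Egr2, Hspa1a, Egr1, Hspa1b, Dnajb1 and Ier3. The log2 change was -1.70 for Hspa1a, -1.67 for Hspa1b and -0.98 for Dnajb1, all genes of the Hsp70 chaperone system. Egr1, an early response transcription factor, went from 233 ± 56.8 to 130 ± 27.9 FPKM (log2 change -0.83). Ier3, a stress-inducible survival gene, went from 2.07 to 0.496 FPKM. Fos, the other well known early response gene, measured 1047 ± 62.3 FPKM in scramble and 1141 ± 549 in shCrebbp (log2 difference 0.01). The values for Jun, Junb and Atf3 were -0.41, -0.16 and -0.15 on the log2 scale. For Atf3 this joins opposite values, at 129 FPKM in scramble, 48.2 in AO228 and 257 in AO229 (limma adjusted p = 0.0305 between the prefixes). Between the prefixes 6 of the 20 members passed when adjusted over the list alone. At an unadjusted p under 0.05, 7 members were higher and 3 lower in AO229 than in AO228.

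The CD40 and NF-kappaB list fell as well, with 17 of 19 members lower and a median log2 change of -0.38 (camera adjusted p = 2.1e-07, 0.0131 with an estimated correlation, and fry adjusted p = 0.0199). All 4 shCrebbp libraries scored below all scramble libraries. Nfkbia and Traf1 passed when adjusted over the list alone, and 0 members passed over all genes. Traf1, a signalling adaptor of tumour necrosis factor receptors, went from 85.6 ± 11.3 to 50.4 ± 12.8 FPKM (SD, n = 4 each; log2 change -0.78). The cytokine gene Tnf measured 23.3 ± 6.48 and 14.2 ± 2.66 FPKM, and the adhesion receptor gene Icam1 40.6 ± 7.70 and 28.9 ± 6.98. Nfkb2 differed by -0.41 and Cd40 itself by 0.17 on the log2 scale. Between the prefixes 3 of the 19 members passed when adjusted over the list alone, and 2, Nfkb1 and Cd80, over all genes. Nfkb1 measured 38.6 FPKM in scramble, 26.4 in AO228 and 54.4 in AO229 (limma adjusted p = 0.0492 between the prefixes). Cd80 went the other way, at 13.3, 15.7 and 4.09 FPKM in the same order (limma adjusted p = 0.0475). Set against the same scramble libraries, AO228 and AO229 gave medians of -0.69 and -0.46 for the immediate early and heat shock list and -0.49 and -0.31 for the NF-kappaB list. With an estimated correlation neither list was called in AO228 (adjusted p = 0.0795 for each) or AO229 (0.252 for each) alone.

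**Figure D2:**
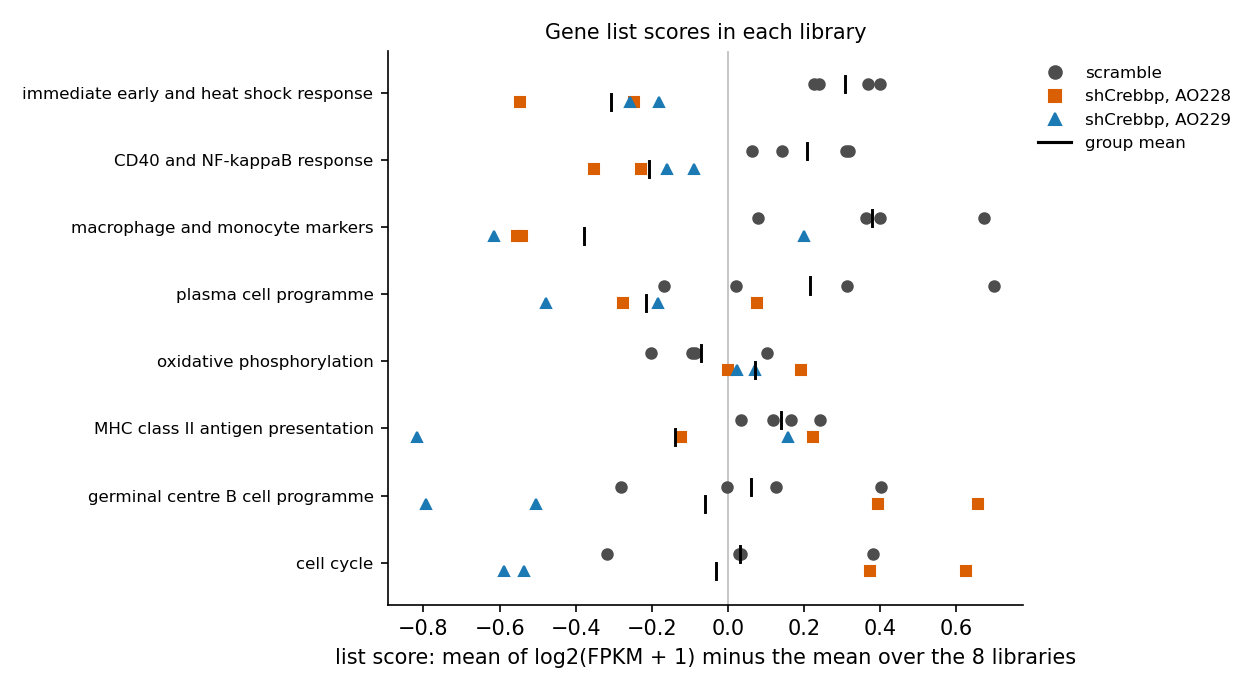
Scores of 8 gene lists (vertical axis) in each library, as the mean of log2(FPKM + 1) over the members minus its mean over the 8 libraries (horizontal axis, log2 units). Circles are scramble, squares shCrebbp AO228, triangles shCrebbp AO229 and black lines group means; the groups separate for the immediate early and heat shock list and the NF-kappaB list, and the MHC class II score of shCrebbp 3 (-0.82) carries Cd74 listed at 0.

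Of 19 macrophage and monocyte markers with a locus, 14 lay under the filter of 1 FPKM. Of the 5 tested in the B220-sorted cells, 4 were lower in shCrebbp, with a median log2 change of -1.23 (camera adjusted p = 5.9e-04, fry adjusted p = 0.0330). Without the filter the 19 members had a median of -0.05 and the call was lost (camera adjusted p = 0.0831). It was also lost with an estimated correlation (adjusted p = 0.0584). That estimate was -0.03, below the preset 0.01, so a higher correlation was not the reason. All 4 shCrebbp libraries scored below the scramble mean, and shCrebbp 3 stood apart from the other 3 at a score of 0.20. Adjusted over the list alone 3 members passed, against 0 over all genes. Ly6c2, a surface protein gene of inflammatory monocytes, went from 18.1 ± 6.42 to 6.61 ± 2.30 FPKM (n = 4 each). The haem-degrading enzyme gene Hmox1 went from 6.44 ± 3.21 to 1.96 ± 0.946, and Emr1, which encodes F4/80, from 5.92 ± 1.52 to 2.16 ± 1.54 FPKM. Lyz2, the abundant lysozyme gene of myeloid cells, measured 1.52 ± 1.75 and 2.72 ± 2.92 FPKM.

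Genes of the plasma cell programme were lower in shCrebbp cells in 20 of 21 cases (median log2 change -0.35, camera adjusted p = 9.8e-06), a call lost with an estimated correlation (adjusted p = 0.352). All 4 shCrebbp libraries scored below the scramble mean. Tnfrsf17, the gene of the survival receptor BCMA, measured 6.08 ± 3.33 FPKM in scramble and 2.10 ± 1.08 in shCrebbp. Xbp1, a transcription factor gene for secretory capacity, measured 88.1 ± 23.01 and 59.4 ± 14.2 FPKM. Igj, the gene of the immunoglobulin J chain, measured 1434 ± 574 and 779 ± 472. Prdm1, which encodes the plasma cell regulator Blimp-1, differed by -0.76 on the log2 scale (exact permutation p = 0.143). None of these members passed, adjusted over the list alone or over all genes.

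Marker genes of marginal zone, B-1 and memory B cells were lower in 15 of 19 cases (median log2 change -0.44, camera adjusted p = 5.9e-04; adjusted p = 0.352 with an estimated correlation). The list score lay below the scramble mean in 3 of 4 shCrebbp libraries, and with only AO229 libraries the median was -0.06 (adjusted p = 0.486). Myof, a membrane repair gene, went from 22.8 ± 3.23 to 11.5 ± 3.42 FPKM (n = 4 each), the 1 member that passed when adjusted over the list alone, with 0 over all genes. Cd9, a tetraspanin gene, measured 11.6 ± 6.69 and 3.20 ± 2.91 FPKM.

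Targets of the tumour suppressor p53 were lower in 15 of 18 cases (median log2 change -0.14, camera adjusted p = 0.0123; adjusted p = 0.352 with an estimated correlation; 3 of 4 shCrebbp libraries below the scramble mean). Sesn1, a stress response gene, measured 63.8 ± 13.7 and 46.6 ± 7.94 FPKM. The call was lost without scramble 2 (adjusted p = 0.127), shCrebbp 3 (0.107) or shCrebbp 4 (0.0610) and without the filter (0.0766), and with only AO228 libraries the median was 0.00 (adjusted p = 0.968). Lymphocyte migration and adhesion genes were lower in 14 of 18 cases (median log2 change -0.14, camera adjusted p = 0.0371; adjusted p = 0.544 with an estimated correlation; 2 of 4 shCrebbp libraries below the scramble mean). Cxcr3, a chemokine receptor gene, measured 7.44 ± 2.18 and 3.78 ± 1.11 FPKM, and the integrin gene Itgb1 34.7 ± 6.32 and 23.01 ± 7.78. With only AO229 libraries this list lay higher, at a median of 0.27 (adjusted p = 0.384), while AO228 against scramble gave -0.54. Its call was also lost without any of 5 single libraries: scramble 1, 3 or 4 (adjusted p = 0.0726, 0.214 and 0.0818) and shCrebbp 1 or 2 (0.597 and 0.125). It was lost after quantile normalization (adjusted p = 0.0537) and with library weights (median -0.02, adjusted p = 0.337) too. Of these lists 0 members passed, adjusted over the list alone or over all genes.

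Genes of oxidative phosphorylation were higher in shCrebbp cells in 23 of 26 cases (median log2 change 0.17, camera adjusted p = 5.9e-04; adjusted p = 0.389 with an estimated correlation). All 4 libraries scored above the scramble mean, but only 1 above every scramble library (exact permutation p = 0.114 for the score). Sdhd, a subunit gene of succinate dehydrogenase, measured 25.7 ± 5.51 FPKM in scramble and 34.7 ± 3.62 in shCrebbp. Ndufb9, a subunit gene of complex I, measured 35.2 ± 6.45 and 46.9 ± 9.58. Ribosomal protein genes were higher in 22 of 24 cases (median log2 change 0.15, camera adjusted p = 0.0412; adjusted p = 0.786 with an estimated correlation; 3 of 4 libraries above the scramble mean). Rpl7 and Rpl18 differed by 0.33 and 0.32 on the log2 scale. The ribosomal call was lost without scramble 1 (adjusted p = 0.538) or 2 (0.172), and without shCrebbp 1 (0.157), 3 (0.107) or 4 (0.253). It was also lost without the filter (adjusted p = 0.104), with a pseudocount of 0.01 (0.0542) and with only AO228 libraries (0.794). Of both lists 0 members passed, adjusted over the list alone or over all genes.

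Genes of antigen presentation through MHC class II were not called (median log2 change -0.09, camera adjusted p = 0.338). Ciita, the master regulator of these genes, measured 87.9 ± 4.45 FPKM in scramble and 82.1 ± 6.98 in shCrebbp (log2 difference -0.10, exact permutation p = 0.20). H2-Aa, an MHC class II chain gene, differed by 0.04 (exact permutation p = 0.886). H2-Eb2 measured 57.9 ± 8.53 and 43.9 ± 6.71 FPKM. Cd74, the gene of the invariant chain, held 7937, 7475, 10342 and 8913 FPKM in scramble libraries and 7967.5, 7168, 0 and 8983 in shCrebbp libraries. Cd74 and Rn45s, a ribosomal RNA precursor, were both listed at 0 in shCrebbp 3, while Rn45s held 2730 to 9149 FPKM in the other 7 libraries.

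The MHC class I list was not called either (median log2 change 0.10, camera adjusted p = 0.0736). Psme2, a proteasome activator gene, measured 51.1 ± 9.50 FPKM in scramble and 74.1 ± 13.4 in shCrebbp. The B cell identity list had a median change of 0.00 (camera adjusted p = 0.110). Its median was -0.32 with only AO228 libraries (adjusted p = 2.2e-04, preset correlation), while AO229 against scramble gave 0.14. In the fit of all 3 prefixes neither was called with an estimated correlation (adjusted p = 0.162 and 0.743). Cd72, an inhibitory coreceptor gene, measured 149.8 ± 33.8 and 76.2 ± 45.0 FPKM. The germinal centre list had a median of -0.12 (camera adjusted p = 0.501), and Bcl6, its master repressor gene, measured 37.8 ± 11.1 and 35.4 ± 12.5 FPKM. The germinal centre median was 0.50 with only AO228 libraries (adjusted p = 5.6e-05) and -0.82 with only AO229 (5.8e-07), both with the preset correlation. In the fit of all 3 prefixes neither was called with an estimated correlation (adjusted p = 0.286 and 0.252). Genes repressed by BCL6 had a median of -0.21 (camera adjusted p = 0.0839), among them Id2 at 41.9 ± 9.04 and 25.7 ± 8.81 FPKM. The cAMP and CREB response list, whose transcription factor binds CREBBP, had a median of -0.16 (camera adjusted p = 0.0532). It passed the threshold in 11 of 25 alternatives, among them a pseudocount of 0.1 (adjusted p = 0.0445), no filter (0.0274) and a filter at 5 FPKM (0.0358), but not with an estimated correlation (0.459). With only AO228 libraries the cAMP and CREB median was -0.34 (camera adjusted p = 3.2e-05, preset correlation), while AO229 against scramble gave 0.07. In the fit of all 3 prefixes neither was called with an estimated correlation (adjusted p = 0.114 and 0.743). Cited2, a member of this list and the gene of a CREBBP-binding protein, measured 32.8 ± 6.36 and 20.5 ± 5.63 FPKM. Leaving out 1 library brought a call for MHC class I (adjusted p = 0.0214 without shCrebbp 3 and 0.0171 without shCrebbp 4), B cell identity (0.00523 and 0.0380 in the same order) and BCL6-repressed genes (0.0490 without scramble 2, 0.0380 without shCrebbp 4). It did so for the cAMP and CREB list (0.0409 without scramble 2, 0.00185 without shCrebbp 3, 0.0171 without shCrebbp 4), and for germinal centre genes without shCrebbp 1 (0.0142).

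Of the other lists tested, none was called by camera. The adjusted p was 0.526 for cell cycle genes (median log2 change -0.07), 0.426 for MYC targets (-0.01), 0.746 for interferon response genes (0.05) and 0.478 for glycolysis (0.18). The median of cell cycle genes joins opposite values of the prefixes: 0.53 with only AO228 libraries (adjusted p = 5.1e-07) and -0.55 with only AO229 (1.5e-09), both with the preset correlation. In the fit of all 3 prefixes neither was called with an estimated correlation (adjusted p = 0.286 and 0.274). Glycolysis genes had medians of 0.40 (adjusted p = 3.8e-04) and -0.24 (0.0465) in the same order, and adjusted p = 0.138 and 0.398 with an estimated correlation in that fit. Without shCrebbp 2 the cell cycle median was -0.24 (camera adjusted p = 0.00147), and with library weights -0.23 (0.0156). Without scramble 2 and shCrebbp 3 it turned to 0.25 (0.00786). The adjusted p was 0.737 for histone acetylation genes (0.01) and 0.144 for apoptosis genes of the BCL2 family (-0.07). With only AO229 the apoptosis list passed (adjusted p = 0.0486), but not with an estimated correlation in the fit of all prefixes (adjusted p = 0.252). Within the MYC list, Odc1, the enzyme gene that starts polyamine synthesis, went from 323 ± 39.2 to 163 ± 46.0 FPKM (log2 change -1.01). It was the 1 member that passed when adjusted over the list alone, with 0 over all genes. Mki67, a proliferation marker, measured 39.9 ± 20.7 and 35.8 ± 24.1 FPKM, and Irf4, a regulator of B cell activation, 217 ± 45.6 and 176 ± 86.7.

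Markers of other cell types lay mostly under the filter of 1 FPKM. T cell markers (median log2 change 0.07, camera adjusted p = 0.746, and 0.00927 without the filter) had 13 of 20 members under it, Cd3e among them, while Cd2 measured 171 and 202 FPKM. Erythroid markers (0.30, camera adjusted p = 0.682) had 10 under it, and the haemoglobin locus Hbb-b1 and Hbb-bs measured 7.39 ± 7.35 FPKM in scramble and 10.1 ± 7.93 in shCrebbp. Too few members passed the filter to test 6 lists. Members under it numbered 9 of 11 for natural killer cells, 14 of 17 for neutrophils (S100a8 among them), 10 of 14 for dendritic cells, 10 of 11 for megakaryocytes, 17 of 18 for stroma and endothelium and 13 of 16 for early B cell progenitors. Among the members above it, Ly6d of the dendritic cell list measured 293 FPKM in scramble and 253.5 in shCrebbp, and Vpreb3 of the progenitor list 42.5 and 61.7. Immunoglobulin constant regions had 0 of 12 members with a locus of their own.

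The third comparison set the shCrebbp libraries of the 2 name prefixes against each other. The lists of germinal centre and cell cycle genes were lower in AO229 than in AO228, and the list of migration and adhesion genes was higher, by camera with its preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.198, 0.198 and 0.318). S1pr2, a receptor gene that confines cells to the germinal centre, measured 93.4 FPKM in AO228 and 20.5 in AO229 (n = 2 each; log2 difference -2.16, standard error 0.32, limma adjusted p = 0.0359), with 61.5 in scramble. S1pr1, the receptor gene for exit into the circulation, measured 47.4 and 142 FPKM (log2 difference 1.57, standard error 0.22, limma adjusted p = 0.0305).

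In all, limma called 146 loci between the prefixes, 76 higher and 70 lower in AO229, among them 5 of small RNAs. AO228 against scramble gave 0 calls (1286 loci at an unadjusted p under 0.05). AO229 against scramble gave 2 (1127 loci at an unadjusted p under 0.05), Snord65 and Mir7088, both small RNAs listed at 0 in every scramble and AO228 library, chosen here after their values were seen. Genes past the threshold and lower in AO229 included Gcsam, Neil1, Top2a and Ccna2. Top2a, a topoisomerase gene of dividing cells, measured 57.0 and 14.8 FPKM (limma adjusted p = 0.0443). Those higher in AO229 included the gut-homing integrin gene Itgb7 (10.2 and 62.2 FPKM), the activation-induced nuclear receptor gene Nr4a1 (67.9 and 518), Plac8 (57.6 and 457), Cd38 (11.4 and 39.0) and Irf4 (102 and 250). These were picked after their values were seen, as were S1pr1 and S1pr2 among the calls. Mki67, at 56.3 and 15.3 FPKM, and Ccr7, the receptor gene for entry into lymph nodes, at 50.2 and 324, did not pass over all genes (limma adjusted p = 0.0991 and 0.0615).

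By list, 28 of 29 cell cycle genes were lower in AO229 (median log2 difference -1.05, camera adjusted p = 1.1e-14; adjusted p = 0.198 with an estimated correlation), with 2 past the threshold over all genes and 21 when adjusted over the list alone, all lower. Of the germinal centre genes 16 of 20 were lower (median -1.43, camera adjusted p = 9.5e-09; 0.198 with an estimated correlation), with 5 past it over all genes, all lower. Adjusted over the list alone 14 passed, 13 of them lower and Cxcr5 higher. Migration and adhesion genes were higher in 13 of 18 cases (median 1.16, camera adjusted p = 3.0e-04; 0.318 with an estimated correlation), with 3 members past it over all genes and 11 over the list alone, S1pr2 as the 1 lower member in both. The number of loci called moved from 146 to 2 when the prior variance had no trend with expression and to 27 without the filter. It was 3 without scramble 1 or scramble 3, 522 without scramble 2, 8, 15 and 11 without shCrebbp 1, 2 or 3, and 71 without shCrebbp 4. Leaving out a shCrebbp library leaves 1 in its prefix, which is then assumed to vary like the other libraries.

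**Figure D3:**
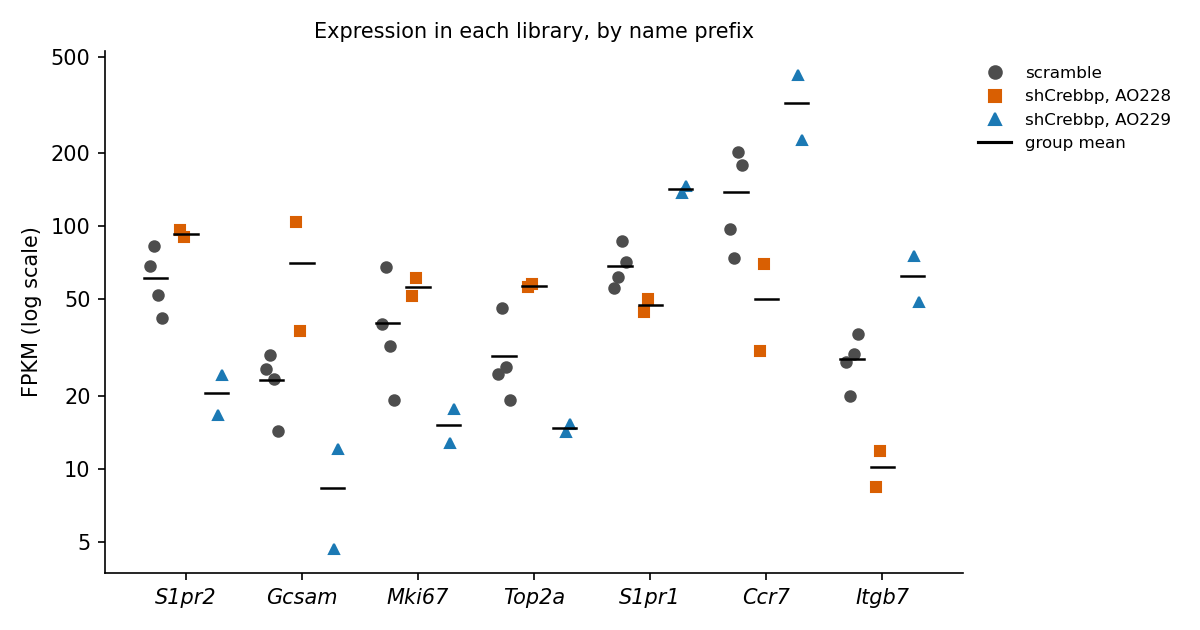
FPKM on a log scale for 7 genes (horizontal axis), with 1 point per library: circles are scramble, squares shCrebbp AO228 and triangles shCrebbp AO229, and black lines are the means of each set. AO228 lies above AO229 for S1pr2 (93.4 and 20.5), Gcsam, Mki67 and Top2a, and below it for S1pr1 (47.4 and 142), Ccr7 and Itgb7.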

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

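Tests chosen only after the result was seen were the count of divisions of the libraries for called genes and for list scores, the macrophage test, and the test of leaving out single libraries of a prefix. Dixon's test marks a value in a group of 4 whose gap to the nearest other value takes most of the range, which happens in about 1 in 20 groups by chance. It was applied to 114 groups and marked 11, where 5.7 are expected by chance.

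The immediate early and heat shock list and the NF-kappaB list were lower in all 4 shCrebbp libraries. Depth and the authors' scaling are argued against as whole causes, since the smaller of the 2 median log2 changes was -0.382 with the share of loci at 0 as a covariate and -0.358 after quantile normalization. Chance cannot be excluded by dividing the 8 libraries otherwise, since these 2 of 23 lists have their largest score difference at the real division, and 7 of 35 divisions hold as many or more, up to 5. A batch or a difference in handling that follows the name prefixes cannot be told apart from the shRNA, since 0 prefixes hold both groups. A lower response to stimulation or stress in cells with shCrebbp may be the biological explanation, and it stays a hypothesis, since the Crebbp transcript itself did not differ detectably.

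The macrophage markers Ly6c2, Hmox1 and Emr1 were lower in shCrebbp cells, although the sort for B220 should remove macrophages. Fewer macrophages rich in C1qa, C1qb, C1qc, Lyz2 and Csf1r are argued against by the low level of these 5 genes. Their median in scramble was 0.685 FPKM, against 5.92 for Emr1, whose lowest scramble value was 4.13. Their median log2 change was 0.02, but at so low a level a fall could hardly show. Fewer monocytes or other cells low in these 5 genes may remain, as may a lower level of Ly6c2, Hmox1 and Emr1 in the lymphoma cells themselves. Neither was tested.

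The AO228 and AO229 libraries differed in cell cycle and germinal centre genes by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.198 for each list). Depth as the whole cause is argued against by a median difference of -1.07 or beyond in both lists with the share of loci at 0 as a covariate. A single library is argued against as well, since leaving out any of the 4 left a median of -0.91 or beyond in both lists. The scramble libraries, which share 1 prefix, also spread widely, with cell cycle scores from -0.32 (scramble 4) to 0.38 (scramble 2). These scores were 0.37 and 0.62 in AO228 and -0.59 and -0.54 in AO229. What the prefixes stand for is not given. Another hairpin, another animal, another batch or spread between single libraries could each be behind the difference (-1.07 with the covariate), and none was tested.

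The real division of the libraries called 0 genes and the highest other 188. Every division gives at least 0 genes (35 of 35), so this count tests nothing. At an unadjusted p under 0.05 the real division gave 573 loci and the highest other 2042, and 11 of 35 divisions gave as many, so chance cannot be excluded for that number. The division with the most calls set scramble 1, scramble 2 and the AO228 libraries against scramble 3, scramble 4 and the AO229 libraries. It points to a structure of the samples and holds the contrast of the prefixes, which alone called 146 loci. Germinal centre scores were 0.13 and 0.40 in scramble 1 and 2, and -0.003 and -0.28 in scramble 3 and 4. They were 0.66 and 0.39 in AO228 and -0.79 and -0.50 in AO229, so for this list the scramble libraries divided in the same direction. Cell cycle scores did so less clearly, at 0.03 and 0.38 against 0.03 and -0.32. The division was picked for its calls, and what lies behind it was not tested. For called lists the real number was 9 and the highest other 13, and 8 of 35 divisions gave as many.

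The difference between the prefixes was called by camera for 9 lists, as the median log2 value of AO229 minus AO228. It was -1.43 for germinal centre genes, -1.05 for the cell cycle, -0.67 for glycolysis and hypoxia, -0.46 for p53 targets and -0.19 for MHC class I. It was 1.16 for migration and adhesion, 1.09 for B cell subset markers, 0.55 for the cAMP and CREB response and 0.29 for B cell identity. With an estimated correlation none of the 9 was called (adjusted p from 0.198 to 0.386).

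Single libraries stood apart from the rest of their group in 11 values. Scramble 2 held 9.37 FPKM of Slc39a4 (others 2.77 to 3.28), 37.9 of the locus of Amigo3 and Gmppb (27.5 to 27.6) and 1.57 of Macrod1 (0.917 to 0.986). It also had 51.8% of loci at 0 (others 42.4 to 43.9%), a p53 target score of 0.29 (0.01 to 0.06) and a first principal component of 96.5 (-18.0 to -7.35), a component that holds 32.97% of the variance. H2-Aa measured 2395 FPKM in shCrebbp 2 (others 3439 to 3651) and Irf4 285 in scramble 3 (191 to 199.8). The MYC target score of scramble 1 was -0.16 (others 0.11 to 0.14). ShCrebbp 3 had a macrophage score of 0.20 (others -0.61 to -0.54) and an erythroid score of 0.74 (-0.13 to -0.03).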

How the results depend on the processing

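The alternatives with a robust prior, with leading loci of single genes, without scramble 2 and shCrebbp 3, and with an exact test of list scores were chosen after seeing the data. The immediate early and heat shock list and the NF-kappaB list kept their direction and their side of the threshold in 25 of 25 alternatives (one, the exact list score, unadjusted at the smallest possible p), with median log2 changes from -0.69 to -0.36 and from -0.49 to -0.30. Other lists kept their call in 22 of 25 (plasma cell, oxidative phosphorylation), 21 of 25 (B cell subsets), 21 of 24 (macrophage), 16 (p53), 14 (migration) and 13 of 25 (ribosomal proteins). Lists not called passed in 11 of 25 (cAMP and CREB), 6 (MHC class I), 5 (cell cycle), 4 (germinal centre, B cell identity) and 3 (glycolysis). With only AO229 libraries the migration list turned to 0.27. The number of lists called (9) was 2 with an estimated correlation, 3 with fry, 2 with the exact list score (unadjusted), 12 without scramble 2 and shCrebbp 3, and 7 to 11 without 1 library. No gene was lower at the threshold in any alternative. Genes changed, all higher, numbered 1 with only AO228 (Mir6992), 3 with only AO229 (Snord65, Mir7088, Mir5128), and 0 to 2 without 1 library, with 2 without scramble 1 (Eaf2, Snord35b) and 1 without shCrebbp 1 (Mir5128). All of these but Eaf2 are small RNAs. List members past the threshold over the list alone (13) numbered 46 with only AO228, 47 with only AO229 and 8 (scramble 1) to 16 without 1 library. Crebbp stayed between -0.31 and -0.09 on the log2 scale and never passed. The 146 loci called between the prefixes became 27 without a filter, 240 at 5 FPKM, 2 without a trend, 495 with library weights, 496 at an adjusted p under 0.1, 243 with a robust prior, 274 with leading loci, 11 without scramble 2 and shCrebbp 3, and 3 to 522 without 1 library (a shCrebbp one left out leaves 1 in its prefix). The cause was not tested, except that a laxer threshold calls more by construction. Counts were not given, so edgeR and DESeq2 were not run, and no comparison by the authors could be repeated. The unknown depth limits genes near 1 FPKM.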

Other observations

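The hypotheses below were tested on gene sets picked after the results were seen, and both tests were chosen then, on the same libraries. Chaperone genes outside the fixed list were also lower in shCrebbp cells. Of 15 cytosolic chaperone genes 12 were lower, 4 of them at an unadjusted p under 0.05 and 0 higher at it. Hsp90aa1, the inducible Hsp90 gene, measured 672 ± 69.8 FPKM in scramble and 406 ± 113 in shCrebbp (SD, n = 4 each). Dnajb4, an Hsp40 cochaperone gene, measured 42.2 ± 13.7 and 19.3 ± 6.78, and Bag3, a gene of chaperone-assisted autophagy, 5.76 ± 2.07 and 2.80 ± 0.508. The chaperonin genes Cct2 and Tcp1 measured 149.8 ± 16.0 and 75.4 ± 3.77 FPKM in scramble and 142 ± 12.6 and 79.4 ± 12.5 in shCrebbp. A lower activity of heat shock factor 1, which drives these genes, may underlie both the chaperones and the heat shock members of the fixed list. The median log2 change of the 15 genes was -0.32, with an exact permutation p of 0.0286 for their score, the smallest possible. These genes were picked after related chaperone genes had been seen to differ between the same libraries, so that p adds no independent support. A difference in handling that follows the prefixes would give the same pattern and stays open.

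Genes of the endoplasmic reticulum stress response were mostly lower too, in 13 of 15 cases. Hspa5, the gene of the chaperone BiP, measured 845 ± 49.8 FPKM in scramble and 588 ± 63.9 in shCrebbp, and Manf, a secreted stress response gene, 44.5 ± 6.44 and 29.8 ± 4.13. A change of the unfolded protein response as a whole may be part of this, with a median log2 change of -0.34. The exact permutation p of the score was 0.257, so the test does not settle it.

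Further genes were picked after the results were seen, the first pair as metal-responsive genes beside Mt1. Mt2 measured 6.46 ± 6.58 FPKM in scramble and 1.21 ± 1.24 in shCrebbp, and the zinc exporter gene Slc30a1 2.37 ± 0.391 and 1.51 ± 0.719. Neither passed limma. Malat1, a nuclear RNA, measured 1344 ± 337 and 921 ± 293 FPKM. Syt1 held 609605 FPKM in shCrebbp 3 and was listed at 0 in the other 7 libraries.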
